A study of Mus musculus with 8 samples.

How the data were processed

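RNA-seq libraries were available for 8 samples of mouse bone marrow hematopoietic stem cells, sorted as Lin-Sca+Kit+CD48-CD150+ and collected directly in Trizol. Per the labels' protocols, cDNA was made with the SMARTer Ultra Low Input kit and libraries with the NEBNext kit, without strand information. Per the submitters' processing notes, TopHat, SAMtools, HTSeq and edgeR were used with the mm9 genome build, with no version stated. The deposited count table holds raw read counts per gene symbol for each of the 8 libraries, as whole numbers with no nameless entries, and all 8 columns were used. The second deposited table holds CPM values: each is the raw count scaled by the library total, to a relative difference of at most 5.1e-15, for the 12457 genes that reach 1 CPM in at least 3 libraries. The annotation and the strand setting of the counting are not given in the sources used here. Samples were grouped by their titles into wild type (3), Mx1-Cre knockout (3) and Vav-Cre knockout (2).

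Total counts ranged from 28689765 to 33202926 per library, of reads without molecular identifiers. Intervals of fold changes come from the edgeR SE and include the spread between libraries. The 10 most abundant genes, led by Actb or Rn45s, took 5.04 to 6.35% of counts. Libraries of the same group correlated across genes at r = 0.954 to 0.978 on log2 CPM, and their counts differed by a chi-square of 28.9 to 134 per degree of freedom, so none was taken for a repeat of another. Between libraries of different groups r was 0.942 to 0.960, which overlaps that range. The 2 Vav-Cre libraries correlated with each other at 0.954. With Mx1-Cre 1, 2 and 3, Vav-Cre 1 correlated at 0.960, 0.956 and 0.957, and Vav-Cre 2 at 0.950, 0.942 and 0.944. TMM factors were 0.961 to 1.03.

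Raw counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test. Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 14086 of 23358, scaled with TMM, and fitted in 1 model over all 8 libraries with group as the only term, so that the groups shared an estimate of spread. The contrasts were both knockout lines averaged with equal weight against wild type, each line against wild type, and Vav-Cre minus Mx1-Cre. Adjusted p-values are Benjamini-Hochberg over all tested genes, a gene was called below 0.05, and the SE is the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, as mean ± SD, and per-library log2 CPM used a prior count of 2.

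The 26 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 26 lists, where at least 5 members were tested. They were also tested with a correlation estimated for each list and with fry, whose test asks whether a list's genes move 1 way on balance without comparing them with other genes. Calls were in addition adjusted over the list alone. The design, the tests, the gene lists, the rule for named genes and all alternatives except library totals as the only scaling were fixed before the data were examined. Named genes were Huwe1, the 10 largest rises and 10 largest falls with both lines averaged and the 5 largest in each direction in the other comparisons, or fewer where fewer passed. These had to be called, with mean log2 CPM of at least 3, at least 4 counts in each group and no overlap between the groups' libraries. To these were added up to 4 members per list with the smallest p and 14 genes fixed beforehand (Myc, Mycn, Max, Cdkn1a, Trp53, Mcl1, Cdkn1c, Flt3, Il7r, Mecom, Ly6a, Kit, Cd48 and Slamf1). Cpa3, Vwf, Plk3, Fas and Plk2, and Lancl3 in the closing section, fall outside that rule and were chosen after their values were seen. Of the genes under the rule, 3 are not reported here.

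The single-gene and list tests were run on simulated counts drawn from the real means and library sizes. The single-gene test covered 13824 genes. With 100 genes changed 2-fold and 100 changed 4-fold, 66% and 96% were recovered with both lines averaged (18 false calls), 57% and 94% for Mx1-Cre (11) and 46% and 89% for Vav-Cre (10). Each gene was drawn with the same spread in all groups. The real groups differed, with a biological coefficient of variation of 21.2% in wild type, 30.5% in Mx1-Cre and 36.1% in Vav-Cre libraries. Recovery and false calls under such unequal spread were not tested. In a separate draw of 14086 genes, for both lines averaged only, a list raised 2-fold was called and 0 of 20 random lists were. Genes were drawn independently there. The draw therefore does not test false list calls where members are correlated, as in the G2/M list (estimated correlation 0.76). Alternatives were DESeq2 1.42.0, limma-voom with quality weights, limma-trend on the deposited CPM with a pseudocount of 1, DESeq2 size factors, upper quartile scaling, other filters (none, or 1 CPM in 2 libraries), a fit of only the groups compared, a replicate block, an adjusted p of 0.1, and each library left out in turn. For both lines averaged, the fit of only the groups compared kept all 8 libraries and treated the knockout libraries as 1 group. Overlap between the lines was set against 100 simulations of all 8 libraries without group differences (random seed 7). In these, both lines shared the simulated wild type libraries, and each gene had the same spread in all groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

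The genome annotation used here was GRCm38 rather than mm9, so no coordinates are given and it served only for chromosome membership and overlap of genes. A chromosome was found for 14032 of the 14086 tested genes (99.6%). Of 204 named genes, 203 were found, and 8 have at least 10% of their exon bases covered by a gene on the other strand, among them Klk8 (24.8%), Cdkn1c (30.7%), Mpo (15.0%), Chaf1a (52.5%) and Fen1 (84.2%). Reads of such pairs cannot be told apart without strand, and counts of families with near-identical copies, such as Gbp, Ifi and Gprasp genes and globins, are uncertain.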

Results

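The series holds RNA-seq counts from mouse hematopoietic stem cells, the rare bone marrow cells from which all blood lineages descend. The cells were sorted as Lin-Sca+Kit+CD48-CD150+ and not cultured. There were 3 wild type libraries, 3 labelled Huwe1 knockout with Mx1-Cre, which deletes upon induction, and 2 labelled Huwe1 knockout with Vav-Cre, which is active in blood cells constitutively. Huwe1 encodes a large HECT-type ubiquitin ligase. The count table gave 23358 genes, of which 5996 had no count in any library and 14086 passed the filter and were tested. Total counts were 29579400, 29758051 and 31338586 in the wild type libraries. They were 33202926, 28704010 and 28947875 in the Mx1-Cre libraries and 28689765 and 31521099 in the Vav-Cre libraries. Genes with at least 1 count numbered 15331, 15474 and 15554 in wild type, 15090, 14749 and 14601 in Mx1-Cre and 14739 and 15170 in Vav-Cre libraries. Every library labelled knockout thus had fewer detected genes than every wild type library. The biological coefficient of variation was 21.2% among wild type, 30.5% among Mx1-Cre and 36.1% among Vav-Cre libraries. The labels do not say that the libraries come from separate animals, so p-values measure only the spread between these samples.

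Huwe1 itself was measured first. Its level was 421 ± 20.5 CPM (mean ± SD, n = 3) in wild type, 418 ± 23.4 (n = 3) in Mx1-Cre and 467 ± 32.2 (n = 2) in Vav-Cre libraries. The log2 fold change against wild type was -0.01 ± 0.11 (SE) in Mx1-Cre and 0.15 ± 0.13 in Vav-Cre libraries. Neither passed the test (edgeR adjusted p = 0.979 and 0.682). The table gives 1 count per gene, so it does not test the loss of some exons and leaves the knockout labels unchecked. Groups are therefore called by their labels throughout. The X-linked transcript Xist had 88 to 323 counts per library and the Y-linked Ddx3y 5904 to 9992.

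To ask which transcripts differed between stem cells labelled Huwe1 knockout and wild type stem cells, the Mx1-Cre and Vav-Cre effects were averaged with equal weight. Fgd5, which encodes a guanine nucleotide exchange factor and is used as a stem cell marker, fell (log2 fold change -3.01 ± 0.24 SE, adjusted p = 0.000562). Its level was 56.2 ± 5.33 CPM (SD, n = 3) in wild type, 3.00 ± 1.20 (n = 3) in Mx1-Cre and 16.2 ± 1.41 (n = 2) in Vav-Cre libraries. The neutrophil granule genes Mpo (-1.89 ± 0.21, adjusted p = 0.00339) and Elane (-2.30 ± 0.49, adjusted p = 0.0369) fell as well. Zmat3, a p53 target that encodes an RNA-binding zinc finger protein, rose from 10.6 ± 1.88 to 46.1 ± 8.89 and 49.8 ± 21.4 CPM (2.17 ± 0.25, adjusted p = 0.00368).

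In all, 373 genes changed, 77 higher and 296 lower, with 34 of the higher and 221 of the lower at least 2-fold. When tested genes were ranked by mean expression into 3 parts of equal size, 130 of 144 called genes were lower in the lowest part and 135 of 162 in the middle part. In the highest part 31 of 67 were lower (46.3%, exact 95% interval 34.0 to 58.9%). Among the largest rises were the cytoskeletal gene Synpo2 (2.59 ± 0.21, adjusted p = 0.000608), the brain-type carnitine palmitoyltransferase gene Cpt1c (2.10 ± 0.21) and the tight junction gene Tjp1 (1.81 ± 0.38). Others were the aspartoacylase gene Aspa (1.66 ± 0.33), the immune regulator Tnfaip8l2 (1.56 ± 0.18), the unnamed gene 9030617O03Rik (1.49 ± 0.25) and the cell cycle inhibitor Cdkn2c (1.26 ± 0.26). Fcer1a, the mast cell and basophil IgE receptor chain, had the largest fitted rise (7.80 ± 1.51, adjusted p = 0.0272). It had 7, 6 and 0 counts in wild type, 227, 411 and 211 in Mx1-Cre, and 57 and 6729 in Vav-Cre libraries, so that 1 library held most of its counts.

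Among the largest falls were Serpinf1, which encodes the secreted factor PEDF (-2.90 ± 0.23, adjusted p = 0.000562), the kallikrein gene Klk8 (-2.80 ± 0.26) and Gprasp2 (-2.69 ± 0.17, adjusted p = 0.000147). Runx1t1, a transcriptional corepressor gene (-2.54 ± 0.36), the kinase genes Alpk1 (-2.49 ± 0.42) and Rps6ka6 (-2.30 ± 0.31), Tinagl1 (-2.33 ± 0.36) and Coro2b (-2.28 ± 0.27) followed. Of 51 genes under the naming rule that passed, 12 did so whichever library was left out. These were Synpo2, Zmat3, Cpt1c, Tnfaip8l2, Fgd5, Serpinf1, Klk8, Gprasp2, Coro2b, Mpo, Ndn and Bgn. Without wild type 1, 2 or 3 the count of changed genes was 113, 22 or 32, and without Mx1-Cre 1 it was 221.

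**Figure D1:**
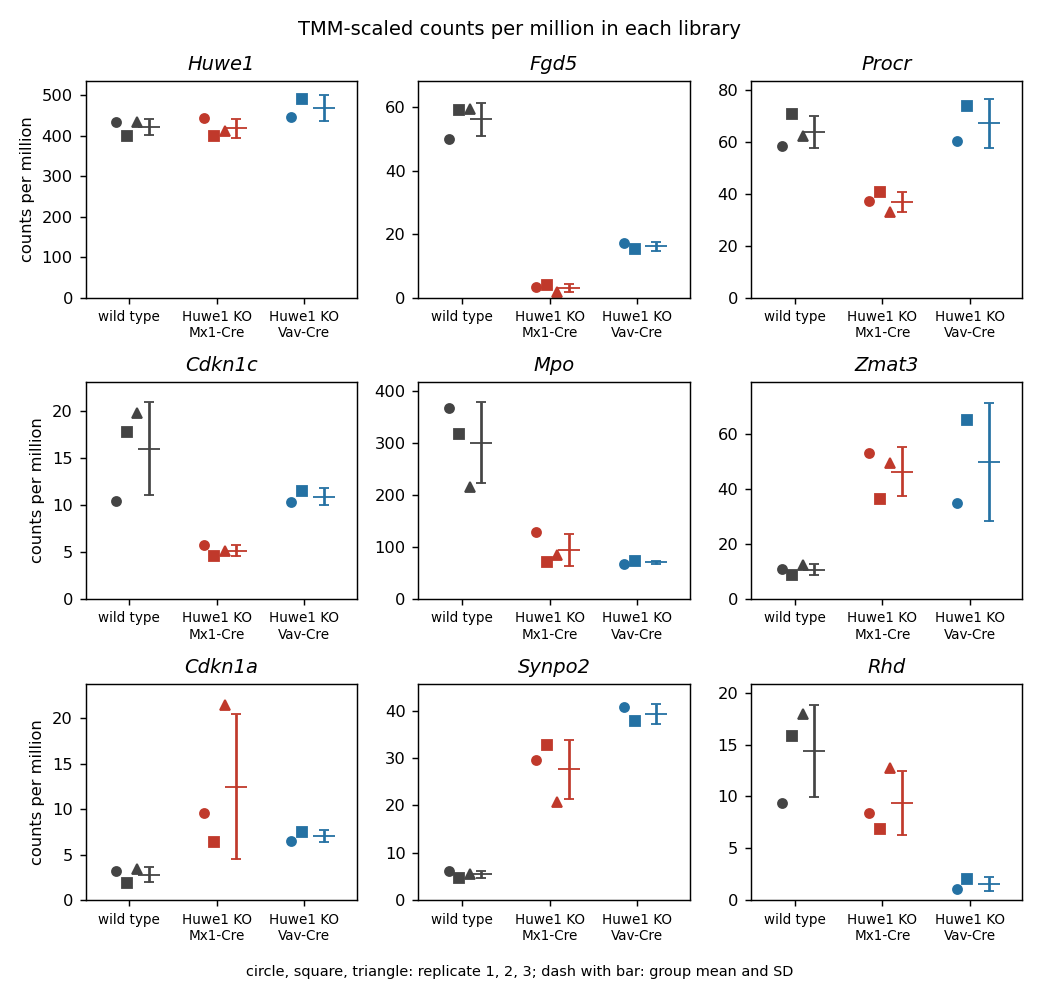
TMM-scaled CPM (vertical axes, linear, from 0) of 9 genes in each wild type (grey), Mx1-Cre (red) and Vav-Cre (blue) library, with circle, square and triangle for replicates 1, 2 and 3 and a dash with bar for the group mean and SD. Huwe1 means lie at 421, 418 and 467 CPM, Fgd5 falls from 56.2 to 3.00 and 16.2, and Zmat3 rises from 10.6 to 46.1 and 49.8.

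Of the 26 gene lists, 10 moved with both lines averaged, 3 up and 7 down (camera, preset correlation, adjusted over 26 lists). With an estimated correlation 0 lists passed, 2 having an unadjusted p under 0.05, and fry called 0. The 30 stem cell identity genes ranked lower (median -0.17, adjusted p = 0.00191). Their list had adjusted p = 0.544 with an estimated correlation. Of its genes 3 fell, among them Fgd5 and the transcription factor gene Gfi1b (-0.71 ± 0.15), 27 did not pass, and 10 were lower adjusted over the list alone. Mecom (-0.21 ± 0.14), Ly6a (-0.26 ± 0.28) and Kit (0.16 ± 0.24) did not pass, nor did Flt3 (-0.09 ± 0.30) and Il7r (-0.74 ± 1.06), receptor genes of progenitors and lymphoid cells. Ribosome biogenesis genes ranked lower, with 47 of 50 folds negative (median -0.15, adjusted p = 0.000126). For this list adjusted p = 0.467 with an estimated correlation. Rrp12 (-0.80 ± 0.16) and Grwd1 (-0.53 ± 0.11) fell, and adjusted over the list alone 2 were lower. In the Mx1-Cre libraries alone this list did not move (22 positive and 28 negative folds, median -0.02, camera adjusted p = 0.564).

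Cell cycle genes ranked higher. The 46 G1/S genes had a median of 0.17 (adjusted p = 0.00113, or adjusted p = 0.638 with an estimated correlation), and the 50 G2/M genes a median of 0.21 (adjusted p = 0.00191, or adjusted p = 0.736 with an estimated correlation). None of these genes passed in edgeR, also when adjusted over the list alone. An unadjusted p under 0.05 was reached by 4 and 2 of them, and DESeq2 called 2 and 0. The 38 p53 target genes ranked higher (median 0.19, adjusted p = 0.0323). For p53 targets adjusted p = 0.467 with an estimated correlation. Zmat3, the stress-induced Trp53inp1 (0.70 ± 0.14) and the death receptor gene Eda2r (1.38 ± 0.27) rose. Adjusted over the list alone 5 were higher, with Cdkn1a and Plk3 (1.02 ± 0.29) added, and 2 lower, Fas (-1.04 ± 0.30) and Plk2 (-0.80 ± 0.23). The cell cycle inhibitor Cdkn1a had 1.74 ± 0.41 (adjusted p = 0.0554) and Trp53 itself -0.10 ± 0.11 (adjusted p = 0.738).

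The quiescence list did not move as a group (adjusted p = 0.757). Its members Ndn, which encodes the growth suppressor necdin (-1.86 ± 0.23), Klf4 (-1.60 ± 0.33), Cdkn1c, which encodes the cell cycle inhibitor p57 (-1.10 ± 0.24), and Gfi1 (-0.95 ± 0.20) fell, while Cdkn2c rose. Adjusted over that list alone 3 were higher and 4 lower. None of the 12 reported HUWE1 substrate genes passed in edgeR, also when adjusted over the list alone (list adjusted p = 0.252). Among them were Myc (0.07 ± 0.14), Mycn (0.51 ± 0.17) and Mcl1 (0.07 ± 0.20). In that list 2 genes had an unadjusted p under 0.05 and DESeq2 called 1. In each line against wild type 0 of its genes passed in edgeR over all genes, and 1 was higher adjusted over the list alone. These are transcript levels, and protein levels of the substrates were not measured.

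Markers of other blood and marrow cells moved beside these groups. The 27 myeloid progenitor genes ranked lower (median -0.64, adjusted p = 0.000379, or adjusted p = 0.553 with an estimated correlation). Mpo, Elane, the G-CSF receptor gene Csf3r (-1.82 ± 0.30), the Fc receptor gene Fcgr3 (-1.82 ± 0.32) and Clec12a (-0.87 ± 0.18) fell, and the mast cell protease gene Cpa3 rose (1.06 ± 0.24). Adjusted over the list alone 2 were higher and 11 lower. The 28 megakaryocyte and platelet genes ranked lower (median -0.28, adjusted p = 0.000142, or adjusted p = 0.544 with an estimated correlation). Mmrn1 (-1.35 ± 0.21), Thbs1 (-1.31 ± 0.27) and F2rl2 (-0.92 ± 0.14) fell, with 2 higher and 10 lower adjusted over the list alone. The 21 erythroid genes ranked lower (median -0.31, adjusted p = 0.0192, or adjusted p = 0.624 with an estimated correlation). The blood group gene Rhd fell (-1.91 ± 0.32), and adjusted over the list alone 5 did.

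Of the 26 mature neutrophil and monocyte genes 25 had negative folds (median -1.56, adjusted p = 6.9e-06, or adjusted p = 0.467 with an estimated correlation). None passed in edgeR, 11 had an unadjusted p under 0.05 and DESeq2 called 4. Adjusted over the list alone Cd68 was higher (0.67 ± 0.18) and 5 were lower, including Retnlg (-2.72 ± 0.67) and Mmp8 (-2.25 ± 0.61). Retnlg lay at 1.77 to 10.5 CPM in wild type, 4.47 to 7.66 in Mx1-Cre and 0 and 0.25 in Vav-Cre libraries. Mmp8 lay at 3.24 to 5.85, at 3.09 to 7.35, and at 0.35 and 0. The falls of these genes, at low levels, thus came from the Vav-Cre libraries. The 20 stroma and endothelium genes ranked lower (median -0.43, adjusted p = 0.0323, or adjusted p = 0.544 with an estimated correlation). The matrix gene Bgn fell (-1.57 ± 0.17), and 3 genes were lower adjusted over the list alone. Without Vav-Cre 1 the stem cell, G1/S, G2/M and erythroid lists no longer passed (adjusted p = 0.0591, 0.767, 0.181 and 0.181), and the G2/M list turned downward. The same was true of the p53, erythroid and stroma lists without wild type 3 (0.0877, 0.0566 and 0.0877), the p53 list without Vav-Cre 2 (0.0750) and the stroma list without Mx1-Cre 3 (0.0664).

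The other lists did not move. Their adjusted p-values (camera) were 0.0630 for the unfolded protein and integrated stress response, 0.0666 for the MYC network, 0.0948 for DNA damage repair and 0.159 for the proteasome. They were 0.222 for the interferon response, 0.222 for immediate early genes, 0.293 for oxidative phosphorylation, 0.323 for the BCL2 family and 0.416 for mature B cells. They were 0.505 for glycolysis, 0.572 for other MYC target genes, 0.613 for T and NK cells, 0.654 for cytosolic ribosomal proteins and 0.931 for lymphoid priming. Single members that fell were Satb1 (-1.43 ± 0.28) and Notch1 (-0.61 ± 0.14), both regulators of lymphoid development, and the glycolytic Eno2 (-2.20 ± 0.46) and Aldoc (-0.72 ± 0.15). The interferon-induced Gbp3 (-1.13 ± 0.22) and the heat shock gene Hsph1 (-1.20 ± 0.22) fell too. Median and mean differed in sign for the quiescence (0.03 and -0.05), BCL2 (0.15 and -0.12), glycolysis (0.08 and -0.05) and T and NK cell lists (-0.17 and 0.23). The lymphoid list (-0.12 and -0.11) tested upward.

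The libraries labelled with the inducible Mx1-Cre were compared with wild type. The titles name no Cre line or inducing treatment for wild type, so effects of either cannot be told apart from those of Huwe1 loss. Fgd5 fell to 3.00 ± 1.20 CPM (-4.22 ± 0.30 SE, adjusted p = 0.000264, n = 3 each). The endothelial protein C receptor gene Procr (-0.79 ± 0.15, adjusted p = 0.0272) fell with it. The inhibitor gene Cdkn1c fell from 16.0 ± 4.95 to 5.13 ± 0.571 CPM (-1.64 ± 0.27, adjusted p = 0.0151). Cdkn1a, which encodes the inhibitor p21, rose from 2.80 ± 0.840 to 12.5 ± 7.99 CPM (2.15 ± 0.45, adjusted p = 0.0352). The test called 351 genes, 55 higher and 296 lower, 26 and 249 of them at least 2-fold. Among the genes with the largest rises were Synpo2 (2.34 ± 0.22), Zmat3 (2.12 ± 0.26), Cpt1c (2.04 ± 0.23) and Aspa (1.57 ± 0.35). Those with the largest falls were Serpinf1 (-3.80 ± 0.28), the zinc finger gene Zfp612 (-3.34 ± 0.45), Klk8 (-3.29 ± 0.32) and Tinagl1 (-3.19 ± 0.44). Of these 8 genes and Fgd5, all but Aspa passed whichever library was left out, as did 14 of the 35 genes under the naming rule that passed here. Cdkn1a and Procr no longer passed without wild type 1, 2 or 3 or Mx1-Cre 1 or 3 (adjusted p 0.0768 to 0.159 and 0.0603 to 0.141), nor Cdkn1c without wild type 2 or 3 or Mx1-Cre 1 (0.0612 to 0.0867). Without wild type 1, 2 or 3 the count was 122, 58 or 61, without Mx1-Cre 1 or 3 it was 98 or 173, and without Vav-Cre 1 or 2 it was 557 or 565.

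In the Mx1-Cre libraries 12 lists moved, 7 up and 5 down. With an estimated correlation 0 did, 2 having an unadjusted p under 0.05, and fry called 0. All 46 G1/S folds were positive (median 0.38, adjusted p = 2.0e-13, or adjusted p = 0.556 with an estimated correlation). All 50 G2/M folds were positive too (median 0.51, adjusted p = 1.2e-14, or adjusted p = 0.568 with an estimated correlation). None of these genes passed singly in edgeR, although 23 and 25 had an unadjusted p under 0.05 and DESeq2 called 9 and 6. Adjusted over the list alone 4 G1/S genes were higher, E2f2 (1.15 ± 0.31), Chaf1a (0.72 ± 0.19), E2f8 (0.71 ± 0.18) and Pold1 (0.51 ± 0.13), and 0 G2/M genes. DNA damage repair genes ranked higher (median 0.29, adjusted p = 4.4e-06, or adjusted p = 0.568 with an estimated correlation). Proteasome genes ranked higher (median 0.18, adjusted p = 0.000156, or adjusted p = 0.568 with an estimated correlation). So did oxidative phosphorylation genes (median 0.15, adjusted p = 0.00447, or adjusted p = 0.684 with an estimated correlation) and other MYC target genes (median 0.09, adjusted p = 0.0335, or adjusted p = 0.630 with an estimated correlation). In these 4 lists 0 genes were called by edgeR, also when adjusted over the list alone, with 11, 2, 1 and 4 at an unadjusted p under 0.05 and 4, 1, 0 and 3 called by DESeq2.

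Of the p53 targets Zmat3, Eda2r (1.39 ± 0.30) and Cdkn1a rose in the Mx1-Cre libraries, with 5 higher and 1 lower adjusted over the list alone. The list ranked higher (median 0.29, adjusted p = 0.0249, or adjusted p = 0.390 with an estimated correlation). Stem cell identity genes ranked lower (median -0.45, adjusted p = 2.1e-08, or adjusted p = 0.390 with an estimated correlation), with 7 of 30 lower and 13 adjusted over the list alone. Interferon response genes ranked lower (median -0.23, adjusted p = 0.0224, or adjusted p = 0.556 with an estimated correlation). Gbp3 (-1.43 ± 0.25), Ifit1 (-1.20 ± 0.24) and Oasl2 (-0.70 ± 0.14) fell, with 2 higher and 9 lower adjusted over the list alone. Singly, Ndn (-2.33 ± 0.27), Notch1 (-0.73 ± 0.16), Eno2 (-2.79 ± 0.55) and Aldoc (-0.82 ± 0.17) fell.

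Markers of other cells ranked lower in the Mx1-Cre libraries beside these groups. In the myeloid progenitor list (median -0.47, adjusted p = 0.00466, or adjusted p = 0.568 with an estimated correlation) Mpo (-1.67 ± 0.25) and Csf3r (-2.30 ± 0.35) fell, with 1 higher and 6 lower adjusted over the list alone. In the megakaryocyte list (median -0.26, adjusted p = 0.0249, or adjusted p = 0.568 with an estimated correlation) Mmrn1 (-1.58 ± 0.24) and the von Willebrand factor gene Vwf (-1.81 ± 0.36) fell. Adjusted over that list alone 1 was higher and 6 lower. In the stroma list (median -0.48, adjusted p = 0.0224, or adjusted p = 0.556 with an estimated correlation) Bgn fell (-1.97 ± 0.20), with 2 lower adjusted over the list alone. The erythroid list (median 0.29, adjusted p = 0.178) and the mature neutrophil and monocyte list (median -0.71, adjusted p = 0.0911) did not move. Other MYC targets, oxidative phosphorylation, p53 targets, interferon response, myeloid progenitor, megakaryocyte and stroma genes each lost the list call in at least 1 fit without wild type 1, wild type 3 or 1 of the Mx1-Cre libraries (adjusted p 0.0555 to 0.681).

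**Figure D2:**
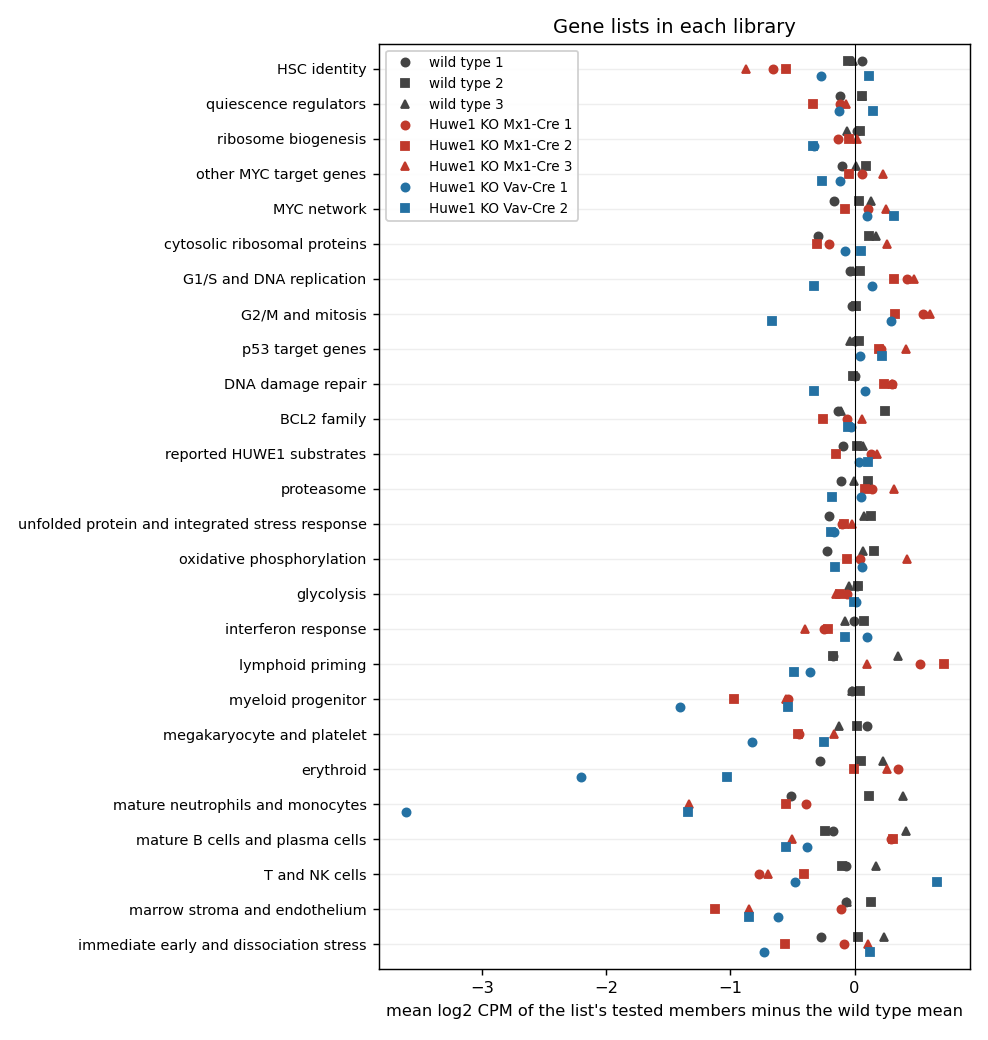
Mean log2 CPM of the tested members of each of 26 gene lists minus the wild type mean (horizontal axis), with 1 point per library, wild type grey, Mx1-Cre red and Vav-Cre blue, and circle, square and triangle for replicates 1, 2 and 3. Stem cell identity lies at -0.66, -0.55 and -0.88 in Mx1-Cre libraries and at -0.27 and 0.12 in Vav-Cre libraries, and the erythroid list at -2.20 and -1.02 in the latter.

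The libraries labelled with the constitutive Vav-Cre were compared with wild type in the same way. The red cell membrane gene Rhd fell (-3.21 ± 0.46 SE, adjusted p = 0.0269). Its level was 14.4 ± 4.45 CPM in wild type (SD, n = 3) and 1.55 ± 0.703 in Vav-Cre libraries (n = 2). The iron exporter gene Slc40a1 (-2.86 ± 0.45), the protease inhibitor gene Serpine2 (-2.64 ± 0.38), Rps6ka6 (-2.64 ± 0.43) and the sodium pump subunit gene Atp1b2 (-2.54 ± 0.44) fell too. Synpo2 (2.85 ± 0.24), Zmat3 (2.23 ± 0.28), Cpt1c (2.16 ± 0.24) and the sorting nexin gene Snx31 (2.12 ± 0.38) rose, as did Fcer1a (9.51 ± 1.62), with 57 and 6729 counts in the Vav-Cre libraries. In all 72 genes passed, 27 higher and 45 lower, 22 and 44 of them at least 2-fold, and with limma-voom the balance turned to 40 higher and 29 lower. Of 25 genes under the naming rule that passed, Synpo2 and Gprasp2 alone did so whichever library was left out. The count was 27, 5 or 12 without wild type 1, 2 or 3 and 196 (103 higher, 93 lower) or 25 without Vav-Cre 1 or 2. It was 38, 121 or 111 without Mx1-Cre 1, 2 or 3, which entered the shared estimate of spread.

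Of the lists 9 moved, 1 up and 8 down. With an estimated correlation 0 did, 3 having an unadjusted p under 0.05, and fry called 1, ribosome biogenesis (adjusted p = 0.0245). All 50 ribosome biogenesis folds were negative (median -0.32, adjusted p = 1.8e-10, or adjusted p = 0.235 with an estimated correlation). Rrp12, which encodes a processing factor of ribosomal RNA, fell (-1.17 ± 0.20), and 2 genes were lower adjusted over the list alone. Other MYC target genes ranked lower (median -0.20, adjusted p = 0.00158, or adjusted p = 0.620 with an estimated correlation). Of these edgeR called 0, also when adjusted over the list alone, 8 had an unadjusted p under 0.05 and DESeq2 called 3. The MYC network ranked higher (median 0.09, adjusted p = 0.0482, or adjusted p = 0.620 with an estimated correlation). Mycn (0.88 ± 0.20, adjusted p = 0.0914 over all genes) and Mnt (0.87 ± 0.20) were the 2 genes higher adjusted over the list alone. The unfolded protein and integrated stress response list ranked lower (median -0.31, adjusted p = 0.00884, or adjusted p = 0.577 with an estimated correlation). Of its genes edgeR called 0, 11 had an unadjusted p under 0.05, DESeq2 called 5, and 7 were lower adjusted over the list alone.

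G2/M genes ranked lower in the Vav-Cre libraries (median -0.10, adjusted p = 0.0440, or adjusted p = 0.914 with an estimated correlation), with 0 called by edgeR or DESeq2, also when adjusted over the list alone, and 0 at an unadjusted p under 0.05. They ranked higher when Vav-Cre 2 was left out (adjusted p = 1.4e-10). Stem cell identity genes did not move as a list (median 0.11, mean -0.02, adjusted p = 0.995), while Fgd5 fell (-1.79 ± 0.31, adjusted p = 0.0376). Markers of mature and committed cells ranked lower beside them. Erythroid genes had a median of -0.89 (adjusted p = 1.4e-07, or adjusted p = 0.306 with an estimated correlation), with 2 lower, among them Rhd, and 9 adjusted over the list alone. Mature neutrophil and monocyte genes had a median of -1.89 (adjusted p = 1.3e-09, or adjusted p = 0.235 with an estimated correlation). Of these edgeR called 0, 9 had an unadjusted p under 0.05, DESeq2 called 7, and 1 was higher and 7 lower adjusted over the list alone.

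Myeloid progenitor genes had a median of -0.81 in the Vav-Cre libraries (adjusted p = 0.000313, or adjusted p = 0.577 with an estimated correlation). Mpo fell (-2.10 ± 0.29), with 2 higher and 9 lower adjusted over the list alone. Megakaryocyte and platelet genes had a median of -0.46 (adjusted p = 5.4e-06, or adjusted p = 0.370 with an estimated correlation). F2rl2 (-1.39 ± 0.18) and Thbs1 (-2.12 ± 0.37) fell, with 2 higher and 9 lower adjusted over the list alone. These 2 lists no longer passed without Vav-Cre 1 (adjusted p = 0.331 and 0.107), nor did other MYC targets and the MYC network without Vav-Cre 2 (0.223 and 0.302). The MYC network call was also lost without wild type 1 or 2 or Mx1-Cre 1 or 3, and the G2/M call without Mx1-Cre 1 or 3 (adjusted p 0.0521 to 0.117).

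Both comparisons against wild type were then set side by side. Synpo2, Zmat3 and Cpt1c rose in each. Fgd5, Mpo, Gprasp2 (-3.09 ± 0.20 and -2.29 ± 0.22) and Rps6ka6 (-1.96 ± 0.36 and -2.64 ± 0.43) fell in each. In all 26 genes were called in both, 6 higher and 20 lower, with 0 in opposite directions, where independent lists of these sizes would share 0.105 and 0.946. Because the wild type libraries are shared, all 8 libraries were simulated 100 times without group differences. Both lines were then compared with the same simulated wild type libraries, so features of the real ones were absent. The simulated lines shared 0.05 calls on average and at most 1. Across genes, which are not independent replicates, the fold changes correlated at r = 0.473 against 0.433 in the simulations. Their covariance was 0.432 against 0.130, a difference of 0.302. Of the 351 genes called in Mx1-Cre libraries 342 (97.4%) had the same sign in Vav-Cre libraries. The simulations called 0.36 genes for Mx1-Cre on average, so there the 351 genes with the smallest p were taken. Of these 87.6% on average, and at most 91.5%, had the same sign. The 2 shares come from genes selected at unlike strength and are not directly comparable. With 3 wild type libraries the controls could not be split, so part or all of any excess over the simulations may come from them. The overlap was 13, 2 or 5 without wild type 1, 2 or 3, 12 without Mx1-Cre 1, and 55 or 14 without Vav-Cre 1 or 2.

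**Figure D3:**
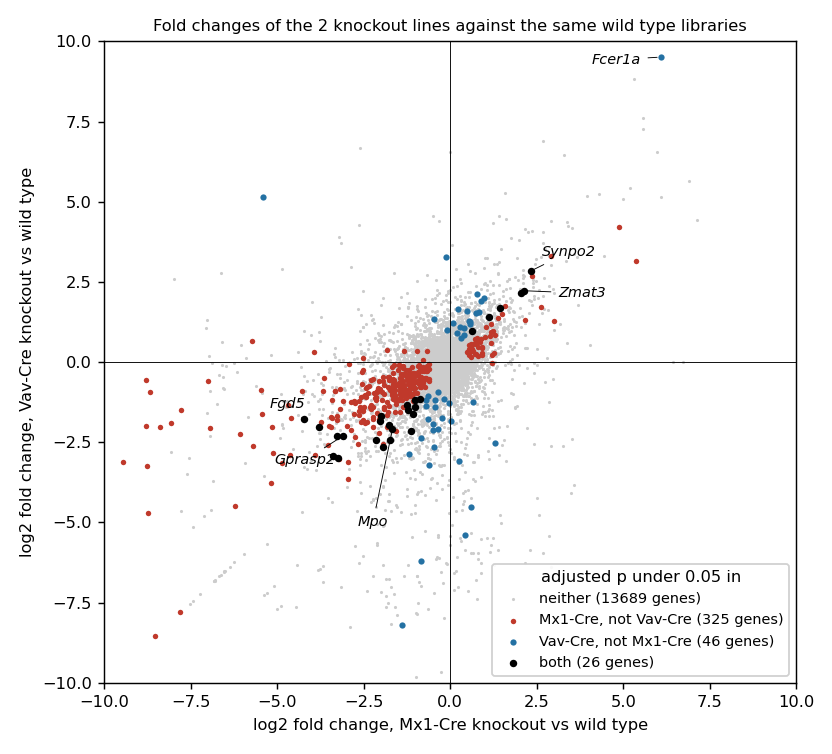
Log2 fold change against wild type of each tested gene in Mx1-Cre (horizontal axis) and Vav-Cre libraries (vertical axis), with 3 genes outside the axis limits of 10. Black points are the 26 genes called in both comparisons, red the 325 called in Mx1-Cre and not Vav-Cre, blue the 46 called in Vav-Cre and not Mx1-Cre and grey the other 13689, and black points lie where both folds have the same sign.

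Finally, the difference between the lines was tested directly as Vav-Cre minus Mx1-Cre. Fgd5 was higher in Vav-Cre than in Mx1-Cre libraries (16.2 ± 1.41 against 3.00 ± 1.20 CPM, SD, n = 2 and 3), with a log2 difference of 2.43 ± 0.30 (SE, adjusted p = 0.0183). Slamf1, which encodes the sort marker CD150 (0.99 ± 0.14, adjusted p = 0.0346), and the ectonucleotidase gene Entpd1 (2.23 ± 0.32) were higher as well. The guanine deaminase gene Gda (1.93 ± 0.30), the meiotic cohesin gene Rec8 (1.81 ± 0.23) and Serpinf1 (1.79 ± 0.29) joined them. Lower in Vav-Cre libraries were Atp1b2 (-3.82 ± 0.47, adjusted p = 0.0183), the mitochondrial fission regulator gene Mtfr2 (-1.88 ± 0.23) and the cilium gene Ccdc40 (-1.51 ± 0.22). In all 24 genes differed, 16 higher and 8 lower in Vav-Cre libraries. The count was 13, 5 or 3 without wild type 1, 2 or 3, 7 or 8 without Mx1-Cre 1 or 3 and 412 or 13 without Vav-Cre 1 or 2. The balance turned as well, with 6 higher and 7 lower, 1 and 4, or 0 and 3 without wild type 1, 2 or 3, 1 and 6 or 3 and 5 without Mx1-Cre 1 or 3, 203 and 209 or 2 and 11 without Vav-Cre 1 or 2, 3 and 6 with a replicate block, and 0 and 3 with only the groups compared. None of the 10 genes under the naming rule that passed did so whichever library was left out.

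Of the lists 14 differed between the lines, 2 higher and 12 lower in Vav-Cre libraries. With an estimated correlation 0 did, 5 having an unadjusted p under 0.05. Stem cell identity genes ranked higher in Vav-Cre libraries (median 0.52, adjusted p = 4.0e-09, or adjusted p = 0.188 with an estimated correlation). Fgd5 and Slamf1 passed, and 15 were higher and 1 lower adjusted over the list alone, among the former Procr (0.86 ± 0.17) and Mllt3 (0.94 ± 0.19). G1/S genes ranked lower (median -0.50, adjusted p = 5.0e-18, or adjusted p = 0.227 with an estimated correlation). Of these edgeR called 0, 22 had an unadjusted p under 0.05, DESeq2 called 8, and 9 were lower adjusted over the list alone. All 50 G2/M folds were negative (median -0.63, adjusted p = 1.1e-22, or adjusted p = 0.263 with an estimated correlation). Here edgeR called 0, also when adjusted over the list alone, 27 had an unadjusted p under 0.05 and DESeq2 called 6. All 50 ribosome biogenesis folds were negative as well (adjusted p = 1.6e-10, or adjusted p = 0.178 with an estimated correlation), with 0 called by edgeR, 9 at an unadjusted p under 0.05 and 2 called by DESeq2. Erythroid genes ranked lower (adjusted p = 1.9e-12, or adjusted p = 0.178 with an estimated correlation), with 1 gene lower and 12 lower adjusted over the list alone. Stem cell identity, ribosome biogenesis and erythroid genes were the 3 lists called by fry (adjusted p = 0.0394 for each). Without Vav-Cre 1 the unfolded protein, interferon, lymphoid, megakaryocyte and neutrophil lists no longer differed (adjusted p 0.0721 to 0.809), the megakaryocyte list turning upward, nor did oxidative phosphorylation genes without Mx1-Cre 3 or Vav-Cre 2 (0.211 and 0.139).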

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

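The tests of other scalings and of RNA from mature cells were chosen after the result was seen, and the other tests in this part were written down before the value they measure. The tests of the difference between the lines singled out 24 genes, Vav-Cre minus Mx1-Cre, among them with log2 differences of 2.43 for Fgd5, 2.23 for Entpd1, 1.93 for Gda, 1.81 for Rec8, 1.79 for Serpinf1, 0.99 for Slamf1, -1.51 for Ccdc40, -1.88 for Mtfr2 and -3.82 for Atp1b2. They also singled out 14 gene lists by camera, none with an estimated correlation (lowest adjusted p = 0.178). Higher in Vav-Cre libraries were the median log2 differences of stem cell identity (0.52) and the interferon response (0.20). Lower were ribosome biogenesis (-0.27), other MYC target genes (-0.29), G1/S (-0.50), G2/M (-0.63), DNA damage repair (-0.36), proteasome (-0.20), unfolded protein response (-0.22), oxidative phosphorylation (-0.21), lymphoid priming (-0.33), megakaryocyte (-0.24), erythroid (-1.20) and mature neutrophil and monocyte genes (-0.63). The groups have 3, 3 and 2 libraries, too few for a test of single outlying libraries.

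With both lines averaged, 296 of 373 called genes were lower. A random grouping of these libraries is argued against for the count. Of 100 splits 1, the real one, gave as many genes, and the highest other gave 174. That split and another with 173 kept the wild type libraries together and mixed the Cre labels. The 97 splits that broke up wild type gave at most 9. These counts bear on chance only if the libraries are independent, which the labels do not state. The choice among the scalings tried is argued against, because the share of lower calls stayed at 78.5% or more under DESeq2 size factors, upper quartile and library totals. These scalings differed little. The median log2 fold change of all tested genes was 0.005, -0.023 and -0.050 under them, against 0.0004 with TMM. Each applies 1 factor per library, so a bias that depends on expression level was not tested by them. Lower complexity of the libraries labelled knockout may account for part of the excess of falls: among the part of tested genes with the highest expression, of 3 equal parts, the share lower was 46.3% (exact lower bound 34.0%), and a lower content of weakly expressed transcripts in the cells themselves, from the knockout, stays open beside it.

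Cell cycle genes ranked higher in Mx1-Cre than in Vav-Cre libraries. The lowest Mx1-Cre library lay 0.11 above the highest Vav-Cre library in the mean of the G1/S and G2/M lists (0.32 against 0.22), so the libraries of the lines did not overlap. Without Vav-Cre 2 both lists still ranked lower in Vav-Cre libraries (camera adjusted p = 4.39e-08 and 5.33e-06), but this leaves a single Vav-Cre library, and with all libraries adjusted p = 0.227 and 0.263 with an estimated correlation. The test had been written to exclude a single deviating library at any gap above 0, but that bound was too weak, because the Vav-Cre libraries lie at 0.22 and -0.50 with an SD of 0.50, larger than the gap. With 2 Vav-Cre libraries, a deviating library and a difference between the Cre lines therefore cannot be told apart.

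Stem cell identity genes ranked lower in Mx1-Cre libraries. RNA from neutrophils, monocytes or stroma is argued against, since the higher of these lists' medians was -0.48, while the erythroid list had a median of 0.29 and RNA from that lineage was not excluded. Multipotent progenitors inside the sort gate may contribute and could not be excluded: Cd48, which the gate sorts against, had a log2 fold change of 0.48 with a 95% interval of 0.10 to 0.87. Of 6 progenitor markers 3 had positive folds, Cd48 alone had an interval above 0, and Satb1 had an interval below 0. An effect of Huwe1 deletion on these genes stays open and untested.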

How the results depend on the processing

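Library totals as the only scaling were chosen after the data were seen. Under the 3 other scalings and the filter of 1 CPM in 2 libraries every total count of genes stayed within 1.5 times its value (the 16 genes higher in Vav-Cre than Mx1-Cre libraries became 25 with upper quartile scaling). So did the counts of lists under DESeq2 size factors and upper quartile scaling. Lists were not tested with library totals as the only scaling. The Huwe1 fold change did not pass in any comparison under any alternative. Values of named genes under the alternatives were counted by whether the main fit called the gene in that comparison. Where it did, 1700 values stayed called in the same direction, 478 fell below the threshold and 0 changed direction. Where it did not, 534 values rose above the threshold in the same direction, and changes of direction were not counted. Calls for both lines averaged, Mx1-Cre, Vav-Cre, the difference between lines and the overlap, in that order, were 953, 1042, 599, 468 and 250 with DESeq2. With limma-voom and quality weights they were 992, 1815, 69, 10 and 40. Fitting only the groups compared gave 177, 575, 111, 3 and 45. The first of these left out no group. It treated all knockout libraries as 1 group, without equal weight for the lines, so a difference between the lines entered the spread. Limma-trend on the deposited CPM gave 513, 604, 146, 28 and 70. Omitting the low-count filter gave 500, 462, 174, 81 and 62, and an adjusted p of 0.1 gave 714, 701, 236, 76 and 97. The cause of these differences was not tested. Leaving out each library gave 22 to 502, 58 to 565, 5 to 196, 3 to 412 and 2 to 55, and 365 or more of the 373 genes kept their sign at an unadjusted p under 0.05. Where this left a single Vav-Cre library, it was taken to vary like the other groups. The 373 genes were selected in these same libraries, so their kept sign lends no independent support. Those short of 373 had failed the filter of that fit. Lists called by camera ranged over 7 to 13, 8 to 13, 7 to 11 and 9 to 15 in these fits. With an estimated correlation 0, 0, 0 and 0 lists were called, and with fry 0, 0, 1 and 3. What depth limits was not tested by thinning counts, and 2-fold changes were recovered in 46 to 66% of simulated genes, drawn with the same spread in all groups.

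The labels give the groups the same replicate numbers. Across 7 pairs of same-numbered libraries the deviations from the group means correlated at -0.07 to 0.13, 1 above 0.1, and 2 of 8 libraries correlated best with their own number, so the numbers were not taken to pair libraries. With a replicate block the calls were 218, 235, 20, 9 and 9.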

Other observations

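The test of whether lower calls concentrate on the X chromosome was chosen after the result was seen, and the other test in this part was written down before. Huwe1 is X-linked, which raised the question whether lower calls favour that chromosome. With both lines averaged, 16 of 516 X-linked genes (3.10%) and 280 of 13512 autosomal genes (2.07%) were called lower, an odds ratio of 1.51 (95% interval 0.85 to 2.52, Fisher's exact test, two-sided, p = 0.117). The hypothesis was neither borne out nor excluded. An interval that includes 1, first taken as enough to reject it, was not, because this interval also reaches 2.52. Chromosome 13, with 16 of 513 genes (3.12%), had about the same share. A lower output of the whole chromosome was argued against: the median log2 fold change of 497 uncalled X-linked genes differed from that of 13158 uncalled autosomal genes by -0.012. Among the X-linked genes called lower were Lancl3 (log2 fold change -3.05 ± 0.40 SE, edgeR adjusted p = 0.00847) and Gprasp2 (-2.69 ± 0.17, adjusted p = 0.000147).

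For the Mx1-Cre comparison the 6 libraries allow 10 splits, of which the real one gave 351 genes and the highest other 2. These are too few splits for a share under 0.05, the real one being 1 of 10.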
